A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

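Cap analysis of gene expression (CAGE), which sequences the capped 5′ ends of RNAs, was measured in whole cells of *Schizosaccharomyces pombe*. The wild type (h- ade6-M210 leu1-32 ura4-D18) and a strain that also carries fft2::kan and fft3::hph had 3 libraries each. Fft2 and Fft3 are paralogous SNF2-family chromatin remodelling ATPases. Per the labels' protocols, cells were grown in YES medium at 30 °C with shaking at 180 rpm and harvested in mid-log growth. The growth protocol speaks of duplicate cultures and the series of triplicates, so libraries of a group may share a culture, and limma p-values measure the spread between libraries only.

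Per the submitters' processing notes, CASAVA 1.6, Bowtie 0.12.7 and bedtools 2.15.0 were used with build ASM294v2, with no roles given. The deposited values are RPM, which the authors scaled to a library total and wrote as TPM, where T stands for tags as usual in CAGE. They are given for the same 108138 tag clusters on chromosomes I to III in every library, so clusters were defined jointly. Each cluster has a strand and a summit, its position of most tags, that is the same in all libraries. The deposited cluster table also holds a pooled score per cluster, a signal that the authors took over all libraries together, and it was not tested. A shift of start sites inside a cluster therefore cannot be seen.

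Between 99.7% and 99.8% of the values above 0 were whole multiples of the value of 1 tag (tolerance 0.02 tags), which gave tags per library. Library totals implied by that step were 20073002, 12681899 and 19765004 tags in wild-type replicates 1 to 3 and 23242897, 23202601 and 19861901 tags in mutant replicates 1 to 3. At 5 TPM, counting error alone was between 9.28% and 12.6% of the value per library. Floors cover counting error only and are minima, since CAGE tags without molecular identifiers are not independent molecules. Intervals of shares and medians reflect the spread between clusters or genes, not between libraries. The floor for a group at 0 is 3 tags over its 3 libraries together, which is 0.0571 TPM in the wild type and 0.0452 TPM in the mutant.

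The annotation available was that of assembly ASM294v3, so its match to the deposited coordinates was tested. With each chromosome divided into 4 equal parts, between 96.3% and 100% of the promoter clusters of a part with a mean of at least 5 TPM had a pyrimidine-purine step, the usual initiator, 1 bp upstream of the summit coordinate, against 23.1% of genome positions. In the same parts, between 70.0% and 81.1% of summits lay 1 bp downstream of the annotated start. Coordinates are given as deposited, counted from 1, and all gene coordinates come from the annotation.

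Clusters were assigned by strand. A gene's promoter window runs on its strand from 500 bp upstream of the annotated start to 100 bp downstream of it. It extends to the start codon where that is further. A promoter cluster has its summit in the window of a protein-coding gene. Remaining clusters within a protein-coding gene were called intragenic on its strand and antisense on the other, with intragenic taking precedence where genes overlap, and all others were called other. Clusters in the window of a non-coding RNA gene were therefore not called promoter. Of those with a mean of at least 1 TPM, 473 were antisense, 293 other and 14 intragenic. A gene's value, coding or not, is the sum of the clusters in its window, and a cluster in several windows went to the nearest start. The annotation held 5113 protein-coding and 7133 lncRNA genes.

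Choices of test, gene lists and rules for named genes were made before the data were examined, except where a later choice is stated below. Clusters and genes with a mean of at least 1 TPM over the 6 libraries were tested with limma 3.58.1 (empirical Bayes with trend) on log2(TPM + 0.5), two-sided, with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are on that scale, which understates the change of low genes, whereas plain folds are ratios of mean TPM. The tag-weighted mean start position was tested with limma without trend in genes with at least 5 TPM in every library. The share of a gene's tags in its main cluster was tested on the logit scale with 0.5 TPM added to each side. Class shares were compared with an exact two-sided permutation test, for which 3 libraries against 3 give 0.1 as the smallest p. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 22 lists, with an estimated correlation as the check. Camera compares a list's genes with all other genes. Fry, the alternative, tests whether a list's genes move in a common direction and does not compare them with other genes. edgeR 4.0.16 and DESeq2 1.42.0 on the recovered tags were alternatives, as were other pseudocounts, filters, windows and scalings, a replicate block and leaving out each library. The labels do not say that replicate numbers mark a shared culture, and same-numbered libraries did not deviate together. Losses with the block may therefore reflect a wrong pairing, or the fewer residual degrees of freedom that a block leaves. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

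The tests were tried on simulated tags for the real features, with 200 features changed in each comparison. For genes (5609 tested), 54% of changes of 1.5-fold were recovered, 92% of 2-fold, 92% of 4-fold and 94% of 8-fold, with 10 false calls. For clusters (11231 tested), the shares were 18%, 90%, 94% and 86%, with 5 false calls. For positions and shares, 40% of the main cluster's tags were moved to the next largest cluster. This was done only in genes with a mean of at least 20 TPM. Then 98.5% of changed positions were recovered among 3710 genes (16 false calls) and 100% of changed main cluster shares among 3709 genes (12 false calls). A single dispersion (0.0183), taken from wild-type genes, was used for all features. The shares for positions and main clusters thus do not carry over to smaller shifts or to genes nearer 5 TPM.

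The genes named are fft1, fft2 and fft3, the 12 largest rises and 12 largest falls among genes past 0.05 whose groups do not overlap, up to 4 members of each list by smallest adjusted p, the 5 largest position changes each way, the 5 largest changes of main cluster share, and the 6 antisense or non-coding clusters with the largest changes. Some are only counted, and a gene among the falls is not reported here. Further genes, named where a count was of 5 or fewer or where a locus is described, were chosen after their values were seen. They are tgp1, gut2, ght1, spo6, mug64, mug115, cox6, atp20, sre1, ade7 and the genes of wild-type replicate 2. No list of pericentromeric genes was run because the annotation gives no centromeres, and no gene of the Tf2 list had the tags to be tested.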

Results

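CAGE tag clusters were compared between wild-type fission yeast and cells lacking both Fft2 and Fft3, with 3 libraries per group. The series asks whether transcription start sites move in this mutant. Libraries held between 12681899 tags (wild-type replicate 2) and 23242897 tags (mutant replicate 1), of which between 91.2% and 92.3% lay in the 108138 clusters. Across clusters, which are not independent replicates, log2 values correlated with a Pearson r of 0.981 to 0.991 within the wild type, 0.984 to 0.989 within the mutant and 0.898 to 0.912 between groups. Values are means ± SD in TPM with n = 3 per group.

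Tags inside the coding part of fft2 fell from 5.11 ± 1.02 to 0.12 ± 0.0460 TPM (272 against 8 tags), and tags inside that of fft3 from 2.56 ± 0.952 to 0.414 ± 0.177 TPM (142 against 27 tags). These changes (log2 -3.17 and -1.71, limma adjusted p = 9.66e-06 and 0.00254) go with the genotype labels. The promoters moved apart. The fft2 promoter fell from 67.6 ± 1.2 to 11 ± 0.763 TPM, whereas the fft3 promoter rose from 71.2 ± 29.2 to 174 ± 47.4 TPM (log2 1.32, adjusted p = 0.0155), a call that ended without wild-type replicate 1 (adjusted p = 0.0520). A cluster 86 bp upstream of the fft3 start rose from 0.932 ± 0.131 to 24.2 ± 1.94 TPM. The promoter of the paralog fft1 had 22.4 ± 2.54 TPM in the wild type and 22.3 ± 1.62 in the mutant.

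The largest rises among coding genes on the tested log2 scale were those of dmc1, pho1 and shu1. The acid phosphatase gene pho1 rose 29.0-fold, from 70.6 ± 2.84 to 2049.5 ± 808 TPM. The heme uptake gene shu1 rose from 0.0672 ± 0.0774 to 14.2 ± 0.0254 TPM, the meiotic recombinase gene dmc1 from 0.801 ± 0.517 to 36 ± 9.71 and the enolase gene eno102 from 3.77 ± 2.76 to 77.5 ± 5.76. Among coding genes past the threshold, the largest fall on that scale was that of gir2, from 41.0 ± 2.26 to 4.05 ± 0.659 TPM (10.1-fold), while by plain ratio the low genes SPBC2A9.03 (32.0-fold) and bsu1 (11.4-fold) fell more. The aldehyde dehydrogenase gene atd2 fell from 19.9 ± 3.64 to 3.04 ± 0.530 TPM, hem14 of heme synthesis from 43.4 ± 8.70 to 7.42 ± 0.891 and pro2 of proline synthesis from 123 ± 24.2 to 22.1 ± 3.65. The non-coding RNA SPNCRNA.1079 fell from 6.04 ± 0.660 to 0.0623 ± 0.0333 TPM.

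**Figure D1:**
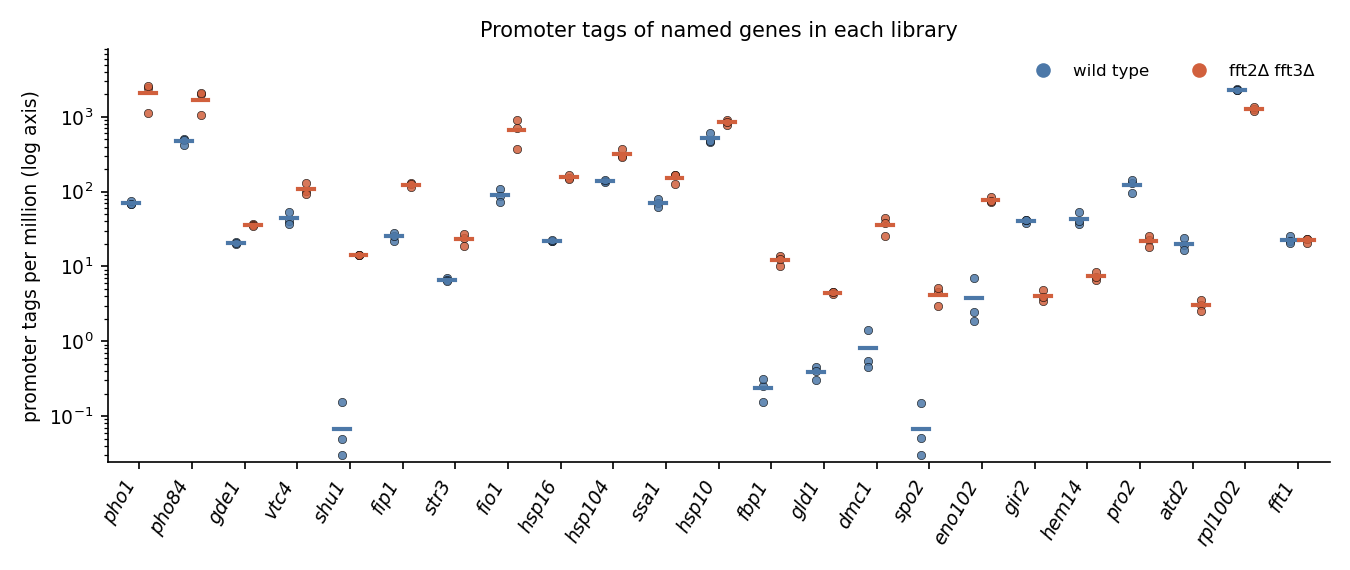
Promoter tags of named genes in each of the 3 wild-type and 3 mutant libraries, in TPM on a log axis, with a library without tags drawn at the bottom of the axis. The mutant libraries of pho1 lie above its wild-type libraries (means 2049.5 and 70.6 TPM) and those of gir2 below (4.05 and 41.0 TPM).

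In all, 1873 of 5610 genes changed (limma, Benjamini-Hochberg), 1362 higher and 511 lower, and 790 changed at least 2-fold (669 higher, 121 lower). The number lower was 332 without wild-type replicate 1, 309 without mutant replicate 3 and 285 with a replicate block. Among coding genes 792 were higher and 452 lower of 4685, which became 293 lower without wild-type replicate 1, 514 higher without mutant replicate 2, and 519 higher and 265 lower without mutant replicate 3. Groups did not overlap in 47.8% of genes, where chance gives 10%. The split of directions rests on the scaling: median-of-ratios scaling gave 953 higher and 989 lower, TMM 895 and 1180, edgeR 1022 and 834 and DESeq2 1079 and 947. For coding genes, median-of-ratios scaling gave 422 higher and 901 lower, and TMM 377 and 1082. The median log2 fold change of all genes was 0.13 as deposited, -0.07 with median-of-ratios scaling and -0.12 with TMM, and some list medians are also given relative to 0.13.

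The phosphate response list rose: 5 of its 7 measured members were higher and none lower (6 and 0 adjusted over the list alone). Besides pho1, the phosphate transporter gene pho84 rose from 474 ± 42.6 to 1698.5 ± 568 TPM, vtc4 from 44.1 ± 8.91 to 108 ± 20.5 and gde1 from 20.4 ± 0.653 to 36 ± 1.04, and the fifth was tgp1 (11.9 to 94.3 TPM). The median log2 fold change was 1.29, or 1.16 relative to all genes (camera adjusted p = 0.0194, and adjusted p = 0.219 with an estimated correlation). Of 12 genes of iron uptake and regulation, 6 were higher and none lower (7 and 0 adjusted over the list alone). The iron permease gene fip1 rose from 25.4 ± 3.08 to 123 ± 7.89 TPM, its ferroxidase partner fio1 from 88.9 ± 18.2 to 657 ± 264 and the siderophore transporter gene str3 from 6.66 ± 0.365 to 23.1 ± 4.09. The list median was 0.45, or 0.32 relative to all genes (camera adjusted p = 0.0222, and adjusted p = 0.260 with an estimated correlation). Both list medians stayed above 0 with either scaling.

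Heat shock genes were among those that rose. The small heat shock protein gene hsp16 rose 7.14-fold, from 21.9 ± 0.379 to 156 ± 9.98 TPM, the disaggregase gene hsp104 from 138 ± 5.18 to 320 ± 41.0 and the Hsp70 gene ssa1 from 71.5 ± 8.97 to 153 ± 24.1. Of 19 chaperone genes, 7 were higher and none lower, also when adjusted over the list alone (camera adjusted p = 0.0354, and adjusted p = 0.225 with an estimated correlation). Median-of-ratios scaling gave 4 higher chaperone genes and TMM 3. The chaperone call ended with median-of-ratios scaling (adjusted p = 0.0575), with TMM (0.0692), without wild-type replicate 1 (0.0609) and without mutant replicate 3 (0.0685). Of 20 core stress genes, 10 were higher and 1 lower, also over the list alone, with gst2 rising from 39.8 ± 8.94 to 98.1 ± 17.5 TPM and the phosphatase gene pyp2 falling from 2.98 ± 0.668 to 0.788 ± 0.122. That list missed the threshold (camera adjusted p = 0.0695, and adjusted p = 0.483 with an estimated correlation), and 6 were higher without wild-type replicate 1, without mutant replicate 3 or with either scaling. It passed in camera without wild-type replicate 2 (adjusted p = 0.0127), without mutant replicate 1 (0.0351) and with a replicate block (0.0306). It also passed with median-of-ratios scaling (0.0317), with TMM (0.0239) and with fry (adjusted p = 0.00256). Wild-type replicate 2 stood apart, with 25 genes over 4 times above both other wild-type libraries and no such gene in any other library, among them the core stress gene zym1 (53.6 TPM, against 9.17 and 9.11).

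Ribosomal protein genes fell: 79 of 131 were lower and none higher (95 and 0 adjusted over the list alone). The promoter of rpl1002 went from 2303 ± 66.9 to 1274 ± 75.9 TPM, rps21 from 678 ± 32.0 to 372 ± 34.5, rps1902 from 268 ± 31.1 to 132 ± 14.9 and rpl1603 from 97.0 ± 4.95 to 39.9 ± 1.6. The median log2 fold change was -0.53, or -0.66 relative to all genes (camera adjusted p = 2.49e-27, and adjusted p = 0.219 with an estimated correlation). Without mutant replicate 2 the count was 49 and without mutant replicate 3 it was 50. Of 59 ribosome biogenesis genes 7 were lower and none higher (1 and 0 adjusted over the list alone), among them gar1, from 404 ± 16.2 to 277 ± 14.2 TPM (camera adjusted p = 2.98e-05, and adjusted p = 0.347 with an estimated correlation). That count was 3 without wild-type replicate 1 and 3 without mutant replicate 3, while median-of-ratios scaling gave 21 and TMM 23. With fry the ribosome biogenesis list missed the threshold (adjusted p = 0.0914).

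Several meiotic genes rose, while their list missed the threshold. Of 20 measured genes of meiosis and sporulation, 9 were higher and 1 (spo6) lower, also over the list alone. With dmc1, spo2 rose from 0.0667 ± 0.0760 to 4.20 ± 1.15 TPM, meu14 from 1.34 ± 0.134 to 6.02 ± 0.320 and rec15 from 0.686 ± 0.124 to 1.89 ± 0.178. The list missed the threshold (camera adjusted p = 0.117, and adjusted p = 0.561 with an estimated correlation). It passed with fry (adjusted p = 0.00187), and in camera with TMM (0.0491) or without wild-type replicate 2 (0.0449). The meiotic regulator mei2 was at 189.9 TPM in that library against 7.42 and 9.61 in the other wild-type libraries. The fall of spo6 was lost without each library except wild-type replicate 2, with 0 lower. Of 64 meiotically upregulated (mug) genes 21 were higher and 2 (mug64 and mug115) lower, or 22 and 2 over the list alone, with mug97 rising from 0.525 ± 0.153 to 9.14 ± 0.590 TPM (camera adjusted p = 0.228). Median-of-ratios scaling gave 15 higher and 5 lower mug genes and TMM 14 and 6, and 4 were lower without mutant replicate 2. For meiosis genes either scaling gave 7 higher and 2 lower.

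Among genes of carbon use, fructose bisphosphatase (fbp1) rose from 0.239 ± 0.0823 to 12.1 ± 1.87 TPM, gld1 from 0.382 ± 0.0732 to 4.48 ± 0.153 and the invertase gene inv1 from 0.304 ± 0.149 to 2.58 ± 0.433. In that list 6 of 13 were higher and 2 (gut2 and the hexose transporter gene ght1) lower, also over the list alone (camera adjusted p = 0.369). The list median was 0.23, or 0.104 relative to all genes, and turned to -0.03 with TMM. Leaving out a library gave medians from 0.0902 (without mutant replicate 1) to 0.379 (without mutant replicate 2). The glycolytic genes gpd3 (237 ± 80.9 to 1143 ± 104 TPM), pgk1 (9413 ± 792 to 15626 ± 1933 TPM) and pgi1 (1758 ± 174 to 2641.5 ± 101 TPM) rose, with 7 of 14 glycolytic genes higher and none lower, also over the list alone (camera adjusted p = 0.228). The glycolytic count was 4 without wild-type replicate 1, 3 without wild-type replicate 2, 3 without mutant replicate 2, 4 without mutant replicate 3 and 3 with median-of-ratios scaling, while TMM gave 2 higher and 1 lower. Of 45 genes of oxidative phosphorylation 3 were higher (sdh3, cox17, atp12) and 3 lower (cox7, cox6, atp20), also over the list alone, and cox7 went from 4.48 ± 1.11 to 1.53 ± 0.289 TPM. Their median was -0.05, or -0.18 relative to all genes (camera adjusted p = 0.0354, and adjusted p = 0.219 with an estimated correlation). With a replicate block atp12 missed the threshold (limma adjusted p = 0.0600). The list's call ended without wild-type replicate 3 (camera adjusted p = 0.0639), mutant replicate 2 (0.0650) or mutant replicate 3 (0.0556). With fry it also missed the threshold (adjusted p = 0.213). The number lower was 1 without wild-type replicate 1 or mutant replicate 3, 5 without mutant replicate 1 or 2, 8 with median-of-ratios scaling (2 higher) and 15 with TMM (2 higher).

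Lists of the proteasome, sterol synthesis, nitrogen uptake, metals and mating missed the threshold. Of 17 proteasome genes 6 were higher and none lower (7 and 0 over the list alone), with rpn2 rising from 117 ± 13.4 to 240 ± 63.8 TPM, and the count was 3 without wild-type replicate 2, 3 without mutant replicate 3 and 2 with either scaling (camera adjusted p = 0.172). Of 21 sterol synthesis genes 7 were higher and 1 (the regulator sre1) lower, also over the list alone, but median-of-ratios scaling gave 1 higher and 4 lower and TMM 1 and 5 (camera adjusted p = 0.798). Without wild-type replicate 1 or 2 there were 4 higher sterol genes, without mutant replicate 2 or 3 there were 2, and sre1 was lost without any library except wild-type replicate 3 (0 lower). Nitrogen and amino acid uptake had 1 higher (amt1) and 3 lower (aat1, fnx1, put4) of 12, also over the list alone (camera adjusted p = 0.552). Its number higher was 4 without wild-type replicate 2, where the amino acid transporter gene isp5 stood at 85.1 TPM against 1.64 and 2.53, and 0 without wild-type replicate 1, mutant replicate 2, mutant replicate 3 or with either scaling. The call of amt1 ended without wild-type replicate 1 (limma adjusted p = 0.0915), wild-type replicate 3 (0.0852, where another gene was higher), mutant replicate 2 (0.0630) or mutant replicate 3 (0.0852). The call of put4 ended without wild-type replicate 1 (limma adjusted p = 0.0653), wild-type replicate 2 (0.0533), mutant replicate 1 (0.119), mutant replicate 2 (0.0573) or mutant replicate 3 (0.0792). The metallothionein gene zym1 was the only higher one of 9 copper and zinc genes (camera adjusted p = 0.685), which became 2 without mutant replicate 1, and 1 was lower without wild-type replicate 2 or with median-of-ratios scaling and 2 with TMM. None of the 4 M-type mating genes passed (camera adjusted p = 0.294), and mfm1 was at 93.8 TPM in wild-type replicate 2 against 0.847 and 6.22.

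P-type mating genes had 1 higher (sxa1) and 1 lower (map1) of 3 (camera adjusted p = 0.722), and sxa1 was lost (0 higher) with either scaling, with a replicate block (limma adjusted p = 0.109) and without any library except wild-type replicate 1. Flocculins and adhesins had 2 higher (pfl4, pfl5) and 2 lower (pfl7, pfl8) of 10 (camera adjusted p = 0.722), with 1 higher under either scaling and without wild-type replicate 1 or 2 or mutant replicate 2 or 3. The wtf genes, which include spore killers, had 1 higher (wtf21) and 1 lower (wtf20) of 7 (camera adjusted p = 0.960). The calls of pfl4 (limma adjusted p = 0.0892) and wtf20 (0.1003) also ended with a replicate block. The fall of wtf20 was lost (0 lower) without wild-type replicate 1 or 3 or mutant replicate 2 or 3, and 2 were higher without mutant replicate 1. Counts of these lists, of copper and zinc genes and of M-type genes were the same when adjusted over the list alone. No histone gene of 10 passed (limma, 0 higher and 0 lower, also over the list alone, camera adjusted p = 0.289), while median-of-ratios scaling gave 1 lower and TMM 4.

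Start sites on the strand opposite to genes had the largest median change of the 4 classes of clusters. A cluster antisense to php5 rose from 0.113 ± 0.119 to 22.4 ± 1.09 TPM, another antisense to the transporter gene fet4 from 0.592 ± 0.382 to 36.3 ± 5.68, another antisense to SPAC922.05c from 0.509 ± 0.0776 to 33.7 ± 2.07, another antisense to sec62 from 0.0930 ± 0.0509 to 19.2 ± 1.12 and another antisense to SPCC1494.01 from 0.244 ± 0.192 to 27.6 ± 4.89. A cluster antisense to fft2 itself (III:186914-186940) was at 0 in the wild type and at 19.8 ± 3.01 TPM in the mutant, at least 347-fold higher against the floor of 3 tags over the group, and lies beside the coding part of that gene (III:183023-186877). The sequence of its kan cassette was not used here, so starts driven by the cassette were not separated from others. The antisense share of all tags went from 0.402 ± 0.00971% to 1.27 ± 0.0605%, and every mutant library was above every wild-type library (exact permutation p = 0.1, the smallest possible). Of 1523 antisense clusters tested, 1146 were higher and 54 lower (median log2 1.74), and 837 genes had an antisense cluster that rose. Median-of-ratios scaling gave 1044 and 111, and TMM 1059 and 100. Non-coding RNA genes followed, with 562 of 899 higher and 57 lower (586 and 68 over the list alone; 94 lower with TMM), a median of 1.11 or 0.98 relative to all genes (camera adjusted p = 4.20e-21, and adjusted p = 0.142 with an estimated correlation). These counts share tags with the antisense class, since 473 of the 1523 antisense clusters tested lie in the promoter window of a non-coding RNA gene. SPNCRNA.1286, whose clusters include the one antisense to SPCC1494.01 given above, rose from 0.618 ± 0.302 to 42.0 ± 3.96 TPM.

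**Figure D2:**
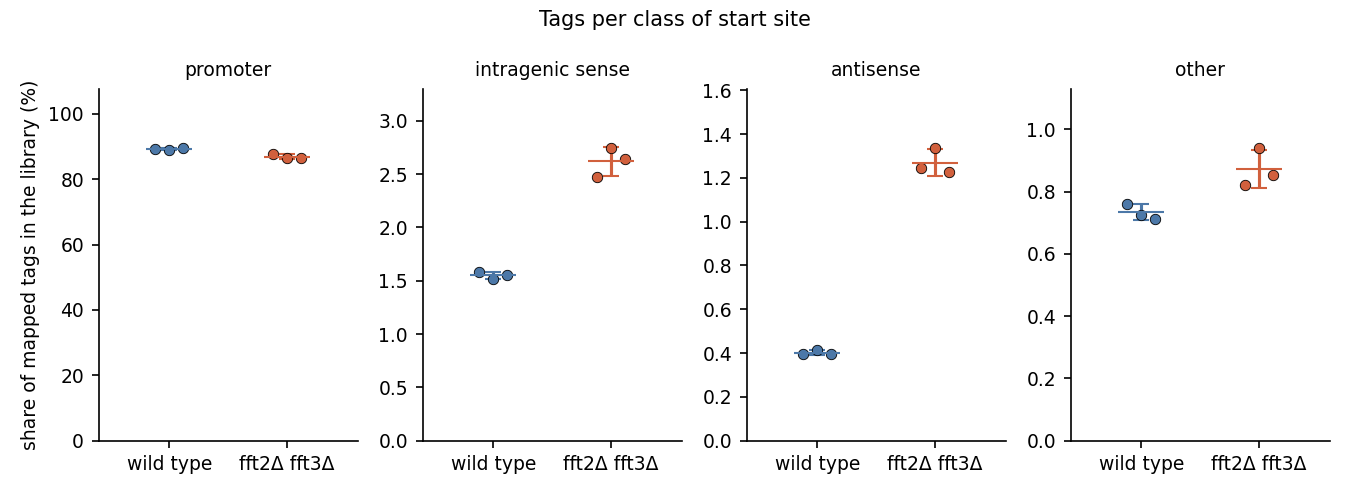
Share of each library's tags, in percent, in promoter, intragenic, antisense and other clusters, with a point per library and the group mean with its SD. The antisense share was 0.402% in the wild type and 1.27% in the mutant, and the intragenic share 1.55% and 2.62%.

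Many start sites inside genes on the sense strand also rose, with a smaller median change. The intragenic share of tags went from 1.55 ± 0.0321% to 2.62 ± 0.137%, and that of other clusters from 0.733 ± 0.0257% to 0.873 ± 0.0621%, while the promoter share went from 89.3 ± 0.371% to 86.9 ± 0.756% (exact permutation p = 0.1 for each, the smallest possible). Of 2922 intragenic clusters 1414 were higher and 90 lower (median log2 0.53), which became 1080 and 280 with median-of-ratios scaling and 1122 and 223 with TMM. Promoter clusters had 1284 higher and 767 lower of 5898 (median 0.08), a direction that turned over with median-of-ratios scaling (547 and 2074, median -0.31) and with TMM (615 and 1663, median -0.23). Other clusters had 304 higher and 142 lower of 907, against 209 and 270 with median-of-ratios scaling and 229 and 244 with TMM. Over all classes 5201 of 11250 clusters changed (limma, Benjamini-Hochberg), 4148 higher and 1053 lower. That split was 2880 and 2735 with median-of-ratios scaling, 3025 and 2230 with TMM, 3082 and 2111 with edgeR and 2898 and 2153 with DESeq2. At an equal depth of 11610135 tags, wild-type libraries had between 44929 and 47475 clusters with a tag and mutant libraries between 66092 and 70051.

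The share of clusters that rose was larger toward the 3′ ends of genes. The share of antisense clusters that were higher went from 37.4% in the first 20% of gene length to 81.7% between 60% and 80%, and was 80.4% in the last 20%. For intragenic clusters it went from 36.3% in the first 20% to 69.1% in the last 20%. The pyrimidine-purine step 1 bp upstream of the summit coordinate was present in 1388 antisense clusters, of which 1101 were higher (median 1.83), and 45 of the 135 without it were higher (median 0.31). Among intragenic clusters 1042 of 1378 with the step were higher (median 1.6) and 372 of 1544 without it (median 0.26). No test of the trend along genes was run.

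**Figure D3:**
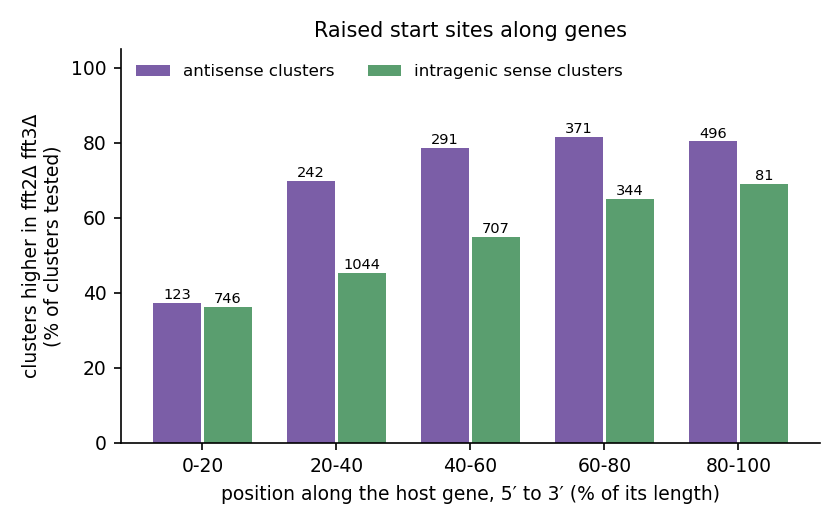
Percent of tested antisense and intragenic clusters that were higher in the mutant, by position along the host gene from its 5′ end in steps of 20% of gene length. The share of antisense clusters goes from 37.4% to 80.4% between the first and the last step, and that of intragenic clusters from 36.3% to 69.1%.

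The hem14 locus (I:276848-278573) shows promoter and opposite-strand clusters together. The hem14 promoter cluster fell from 43.4 ± 8.70 to 7.42 ± 0.891 TPM. On the opposite strand a cluster with its summit at I:277802 rose from 4.04 ± 0.167 to 112 ± 12.5 TPM (log2 4.62, limma adjusted p = 6.14e-07). It lies in the annotated transcript of lsh1, whose strand it shares, and so was counted as intragenic. In gir2 a cluster antisense to the gene (III:815445) was at 0 in the wild type and at 4.83 ± 1.02 TPM in the mutant, at least 84.6-fold higher against the floor over the group. In atd2 an antisense cluster (I:5487958) rose from 0.303 ± 0.128 to 6.81 ± 2.68 TPM.

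**Figure D4:**
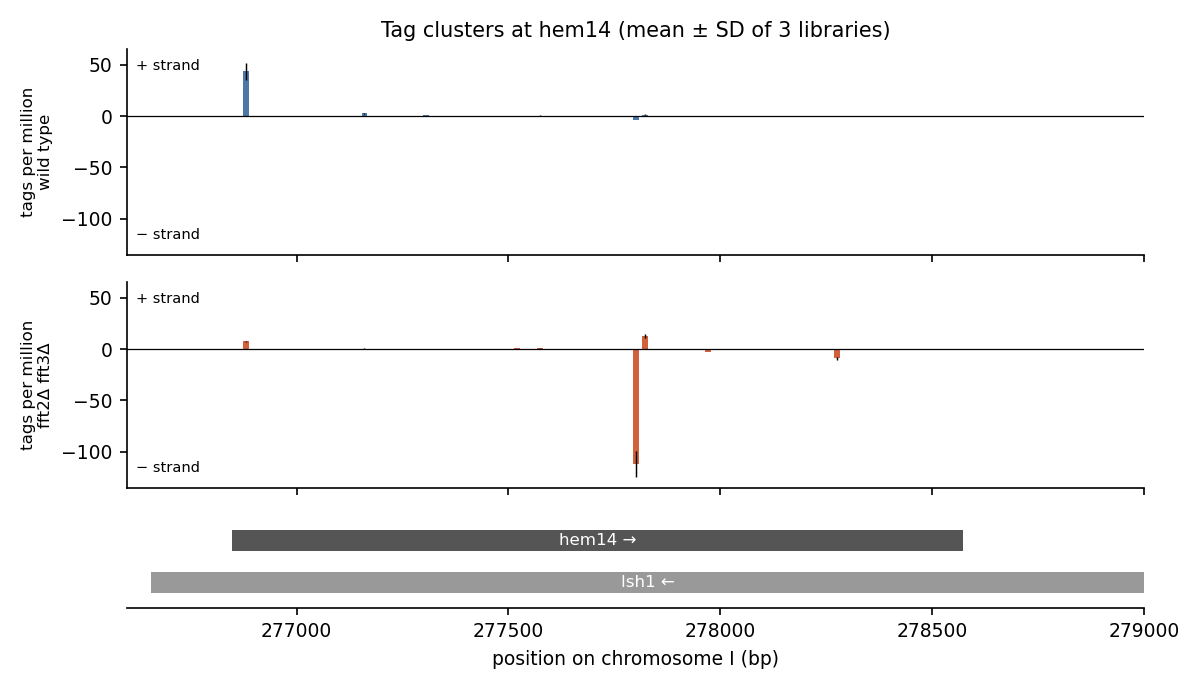
Tag clusters of the hem14 locus by position on chromosome I (bp) and strand, with mean TPM in the wild type and the mutant. The promoter cluster of hem14 fell from 43.4 to 7.42 TPM and the cluster at 277802 on the other strand rose from 4.04 to 112 TPM.

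Mean start positions differed in a minority of genes. Far upstream starts gained weight at ima1, whose mean moved from -131 ± 12.8 to -322 ± 6.14 bp relative to the annotated start, and whose cluster at -493 bp rose from 0.585 ± 0.0540 to 13.7 ± 0.729 TPM. At SPBC530.07c the mean moved by -188 bp, as the cluster at the annotated start fell from 44.1 ± 4.12 to 1.97 ± 0.464 TPM and the cluster at -395 bp from 33.1 ± 2.09 to 24.4 ± 1.22 TPM. The mean of rsp1 moved by -262 bp, cao1 by -165 bp and fap1 by -125 bp. Downstream moves were 281 bp at SPCC777.03c, 215 bp at SPCC794.06, 211 bp at the phospholipase gene plb2, 495 bp at SPAC2H10.01 and 530.4 bp at stb3, whose cluster at 851 bp rose from 1.11 ± 1.10 to 21.2 ± 7.06 TPM. The narrower window ran from 200 bp upstream to 50 bp downstream of the annotated start. It leaves out clusters of ima1 (-493 bp), SPBC530.07c (-395 bp), fap1 (-261 bp), rsp1 (473 bp), stb3 (851 bp) and SPCC777.03c (920 bp). Shifts that rest on these clusters could not be retested with it. With that window the shift of SPAC2H10.01 was -0.0919 bp, and those of cao1 and plb2 were no longer past the threshold (adjusted p = 0.585 and 0.967, limma). With weighted medians, fap1 (adjusted p = 0.389) and SPAC2H10.01 (0.181) were not past it. With the replicate number as a block, ima1 alone of these 10 genes passed, and the others had limma adjusted p from 0.0507 (SPBC530.07c) to 0.165 (fap1). Same-numbered libraries did not deviate together, so that block rests on no pairing seen in the data. Single libraries ended 4 of these calls (limma adjusted p). Without wild-type replicate 1 the values were 0.0548 for cao1, 0.0785 for fap1, 0.0684 for stb3 and 0.0690 for SPCC794.06, and without wild-type replicate 2 that of SPCC794.06 was 0.0623. Without wild-type replicate 3 they were 0.0632, 0.0847, 0.0826 and 0.0531 for the same 4 genes. For cao1, fap1 and stb3 they were 0.0584, 0.0750 and 0.0664 without mutant replicate 1, and 0.0538, 0.108 and 0.0710 without mutant replicate 2. Without mutant replicate 3 they were 0.0713, 0.104 and 0.0767, with 0.0616 for SPCC794.06.

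Of 3966 genes with at least 5 TPM in every library, 3539 had a computed mean position that was not identical in all libraries and were tested. Only 3513 genes had more than 1 cluster, so some genes tested differed by rounding alone. Of the 3539, 520 passed (limma, Benjamini-Hochberg), 314 upstream and 206 downstream. The median size of the shift was 0.763 bp, beside a median SD within groups of 0.689 bp, and 85.7% of the 3539 genes, past the threshold or not, shifted by under 10 bp. Shifts of at least 10 bp that passed numbered 262 (130 upstream, 132 downstream) and of at least 50 bp 86. The counts past the threshold and past it by at least 10 bp were 216 and 125 without wild-type replicate 1, 285 and 172 without wild-type replicate 2, 253 and 142 without wild-type replicate 3, 304 and 150 without mutant replicate 2, and 300 and 143 without mutant replicate 3. They were 234 (191 upstream, 43 downstream) and 63 (43 upstream, 20 downstream) with the narrower window, 31 and 23 with a replicate block and 30 and 30 with weighted medians. The cluster with most tags differed between the groups in 55 genes (1.39%; 25 upstream, 30 downstream), against 18 to 36 genes between libraries of the same group and 57 to 68 between libraries of different groups. At ade7, of purine synthesis, it moved from the annotated start (69.4 ± 7.40 to 35.4 ± 5.52 TPM) to a cluster at -169 bp (11.3 ± 1.21 to 51.3 ± 6.66 TPM). Positions are cluster summits, so shifts within a cluster were not measured.

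**Figure D5:**
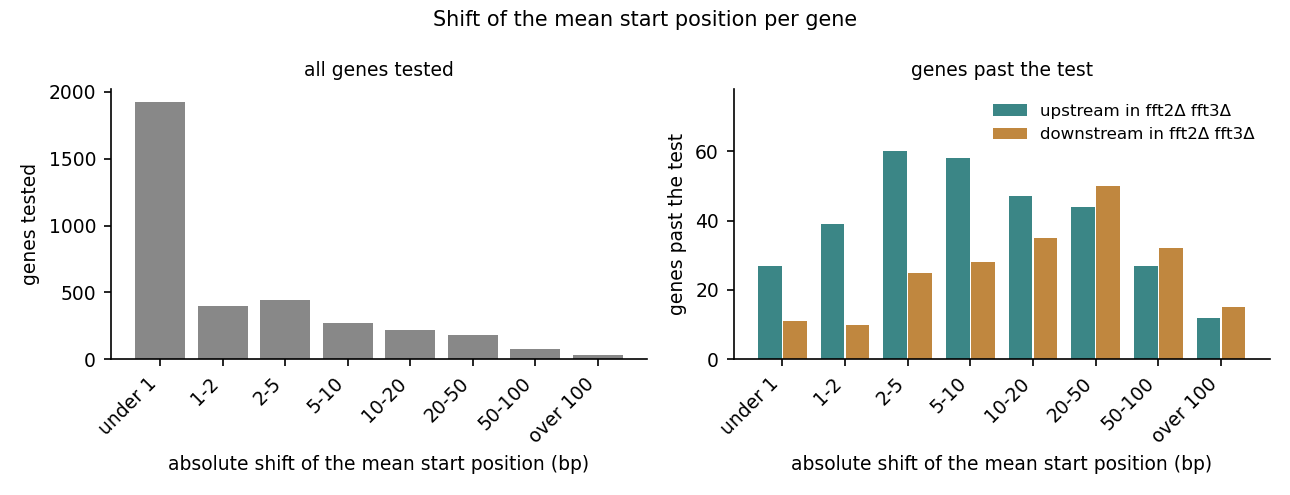
Number of genes by the size of the change in mean start position between mutant and wild type, in bp, with those past the threshold upstream and downstream. Of 3539 genes 1925 shifted by under 1 bp and 30 by over 100 bp.

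The share of tags in a gene's main cluster changed in 1010 of 3513 genes with more than 1 cluster, lower in 729 and higher in 281 (limma, Benjamini-Hochberg), and by at least 10 percentage points in 224. With 0.1 TPM added in place of 0.5 the numbers were 666 lower and 163 higher. It rose from 9.30 ± 6.29% to 74.2 ± 2.21% at SPAC32A11.02c, from 13.4 ± 11.7% to 74.7 ± 3.32% at stb3 and from 88.9 ± 6.91% to 99.5 ± 0.0383% at ddr48. It fell from 97.8 ± 0.472% to 72.5 ± 1.79% at erp2. At pho1 it went from 99.7 ± 0.0943% to 99.98 ± 0.0119%, while the tested logit rose by 4.52 (log2), close to the rise of its promoter (log2 4.76). The median share over the genes tested was 99.4% in the wild type and 99.0% in the mutant. Many genes thus had few tags outside the main cluster. Where those are near the added 0.5 TPM, the tested logit can follow the gene's level, so some calls may not reflect start site usage.

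Fft3 is known to act near the ends of chromosomes I and II. Within 100 kb of these ends 83 of 116 clusters changed (71.6%, against 46.0% elsewhere), 60 higher and 23 lower. Their median log2 was 0.63 against 0.27 elsewhere. By class, medians near the ends were 0.46 for promoter clusters (0.0810 elsewhere), 1.41 for intragenic (0.525) and 0.63 for antisense (1.75) and 0.0578 for other clusters (0.223), so the first pair was above and the last pair below the values elsewhere. Camera did not set the clusters within 100 kb apart (p = 0.811, and p = 0.920 with an estimated correlation). The 3 clusters within 50 kb, all higher, had a median of 2.10 (camera p = 0.0207, and p = 0.162 with an estimated correlation). No promoter cluster within 20 kb had the tags to be tested, and only 2 between 20 and 40 kb did (median 1.98). Further in, promoter medians were 0.490 (40 to 60 kb), 0.737 (60 to 80 kb) and -0.191 (80 to 100 kb). Of 47 subtelomeric coding genes 24 were higher and 7 lower (27 and 10 over the list alone), among them cmt2, which rose from 0.700 ± 0.215 to 21.4 ± 0.455 TPM, and SPAC977.15, from 1.09 ± 0.242 to 10.02 ± 0.862. Pho1 and shu1 also lie there, and SPBPB10D8.01 fell from 12.6 ± 4.26 to 1.53 ± 0.485 TPM. The list missed the threshold (camera adjusted p = 0.172, and adjusted p = 0.706 with an estimated correlation). It passed with fry (adjusted p = 0.00362). In camera it passed with median-of-ratios scaling (0.0211, 21 higher and 11 lower), with TMM (0.0114, 21 and 12) and without wild-type replicate 2 (0.0346). In that library the urea transporter gene SPAC869.03c stood at 150.2 TPM against 0 and 3.19 in the other wild-type libraries. Tf2 retrotransposons had 3 clusters, all upstream of Tf2-11, with 0.398 ± 0.269 TPM in the wild type and 0.884 ± 0.281 in the mutant (exact permutation p = 0.2). Near-identical copies make that assignment uncertain. Clusters in long terminal repeats summed to 16.05 ± 1.10 and 24.8 ± 4.48 TPM (exact permutation p = 0.1, the smallest possible).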

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

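Rescaling, blocking and leaving out libraries for antisense, intragenic and promoter clusters, TMM for the gene lists, the estimated correlation within 50 kb and the alternatives for shifts of at least 10 bp were chosen after seeing the data; all other alternatives were planned. Over results that answer a comparison, 136 alternatives were scored as unchanged, 32 moved a value, 1 took a result past the threshold and 1 reversed. Counts were scored by their total alone, without regard to direction. The gene count with TMM, 895 higher and 1180 lower against 1362 and 511, was thus scored as unchanged. For single lists, genes and positions, 1288 changed nothing, 111 ended a call, 20 made 1 and 1 reversed. Where a cause is not named, the cause was not tested.

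Filters and windows change how many features are tested. Changed clusters numbered 17753 without a filter, 1759 with a mean of at least 5 TPM and 2972 with a change of at least 2-fold, against 5201. Changed genes numbered 3391, 1121 and 790 in the same order and 2947 with tags of the gene body added, against 1873. The estimated correlation left 0 of the 7 list calls. Fry gave 12, without ribosome biogenesis and oxidative phosphorylation. It added the core stress, carbon, meiosis, mug, glycolysis, proteasome and subtelomeric lists. Fry does not compare a list with other genes, and 11 of its 12 calls were higher, beside a median of 0.13 over all genes. Its calls thus answer another question than those of camera. With scaling, calls in the same direction as before numbered 3933 (median-of-ratios) and 4078 (TMM) of the 5201 clusters and 1464 and 1406 of the 1873 genes, and none had the opposite direction.

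Changed start positions numbered 324 with at least 20 TPM in every library, 234 with the narrower window, 31 with a replicate block and 30 with weighted medians, against 520. Those of at least 10 bp numbered 108, 63, 23 and 30 against 262. Leaving out a library gave 216 to 455 changed positions, and 125 to 225 of at least 10 bp. The shift of SPAC2H10.01 reversed to -0.0919 bp with the narrower window, which leaves out its distant clusters. With at least 20 TPM, changed main cluster shares numbered 586, and the main cluster moved in 16 of 2467 genes (0.649%), against 55 of 3966 (1.39%).

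The rise in the antisense share was 0.531 percentage points and in the intragenic share 0.682 over clusters with a mean of at least 1 TPM, which leaves out low clusters, against 0.867 and 1.07. The rise of other clusters was 0.204 points with the narrower window, which moves promoter clusters into that class, against 0.139. The 3 subtelomeric clusters within 50 kb had a median of 2.10 and passed the test, but not with an estimated correlation (p = 0.162). The coding part of fft3 reverses the direction of its promoter (log2 -1.71). No Tf2 cluster had a mean of at least 1 TPM, so that alternative gave no value.

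Leaving out a library gave 4346 to 5078 changed clusters, 1354 to 1810 genes, 5 to 10 lists, 693 to 940 main cluster shares and 78 to 85 of the 95 named genes past the threshold, against 88.

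With the replicate number as a block, 4386 clusters, 1252 genes, 8 lists and 31 positions changed. Same-numbered libraries did not deviate together (correlations across genes -0.21, -0.21 and -0.34), so no pairing by number was seen. Each library correlated best with another number (0.43, 0.39 and 0.41). Deviations within a group of 3 balance out, so some best match always arises, and these values cannot settle the pairing. Wild-type replicates 1, 2 and 3 correlated best with mutant replicates 2, 3 and 1. That matching was not modelled, and no label gives a batch.

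Depth limits low features, since 5 TPM in wild-type replicate 2 carries a counting error of 12.6%. In simulated data 18% of 1.5-fold changes of clusters and 54% of those of genes were recovered. These shares are over features of all levels, so the losses were not traced to depth.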

Other observations

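Tests of antisense clusters and of intragenic clusters without the initiator step were chosen after their results were seen, as were the other splits of the samples, the interval of the antisense-to-sense difference and its matching on length; the remaining tests were set beforehand.

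In wild-type replicate 2, 25 genes stood over 4 times above both other wild-type libraries, and no theme among them was tested. The urea transporter gene SPAC869.03c stood at 150.2 TPM against 0 and 3.19, its neighbour SPAC869.04 at 118 against 0 and 2.18, isp5 at 85.1 against 1.64 and 2.53, and the thiazole synthesis gene thi2 at 1790.5 against 98.5 and 126. The mating genes mfm1 (93.8 TPM), sxa2 (11.8) and spk1 (31.0) were also among them. In the mutant libraries mei2 lay between 34.2 and 68.7 TPM. The coding part of ura4, which the ura4-D18 allele of both strains lacks, had 0 tags in all 6 libraries, which allows up to 0.0571 TPM in the wild type and 0.0452 TPM in the mutant. Its promoter window had 1.58 TPM in wild-type replicate 2, against 0.0498 and 0.152 in the other wild-type libraries and 0 in the mutant.

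Antisense clusters rose in the mutant. Depth is argued against, since at equal tags the lowest mutant library had 1.39 times as many clusters as the highest wild-type library. Broken RNA or genomic DNA is argued against by the pyrimidine-purine step at 96.1% of the risen clusters (95% interval 94.8 to 97.1%), and scaling by a median log2 fold change of 1.46 (1.36 to 1.53) with median-of-ratios scaling. A candidate explanation that the design names is initiation inside genes in the absence of Fft2 and Fft3, which was not tested further. CAGE tags count the capped RNAs present in the cells, so rates of initiation were not measured and other candidates remain open.

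Intragenic sense clusters rose as well. Clusters with the step rose more than those without by 1.36 (1.28 to 1.48) after the change of the host promoter was taken off, which argues against uncapped RNA as the whole cause. A spread of tags along more expressed genes is argued against for the class as a whole, if narrowly, by a median excess over the host promoter of 0.33 (0.302 to 0.365, set against a bound of 0.3). For clusters without the step the excess was 0.14 (0.118 to 0.157), under a bound of 0.2 that was set after the result was seen. A spread that follows the host promoter predicts no excess, whereas the whole interval is positive. The median host change was 0.11, beside a median rise of 0.26 for clusters without the step. Tags spread along the host transcript may thus be a part of their rise, and the excess argues against them as the whole of it. For clusters with the step the excess was 1.49.

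Genes whose promoters fell may be held down by antisense initiation, a hypothesis drawn from genes such as gir2 and hem14. Among genes matched on wild-type level, the 798 with a risen antisense cluster differed from the 3887 without by -0.0795 in median log2 sense change (95% interval -0.133 to -0.04, p = 0.00017 by permutation of genes). Only clusters of the antisense class counted, so hem14, whose opposite-strand clusters were counted as intragenic, stood among the genes without. Other genes that overlap a neighbour may stand there too. With that grouping, the interval excludes the 0.2 fall predicted. The value lies above the -0.1 set for dropping the hypothesis, but its interval spans that bound, so the test leaves a smaller effect open. For genes placed as hem14 was, the test does not decide. Promoters fell in 15.2% of genes with and 8.52% without a risen antisense cluster. Matched also on gene length, the difference was -0.12 (-0.171 to -0.072, p = 0.0001, the smallest that 10000 permutations can give).

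With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Every other split mixes wild-type and mutant libraries, so the group difference adds to the spread within its groups. A lack of calls in such a split follows from that and does not measure false calls. For each of the following results, 1 of the 10 splits, the real one, gave as many calls. The real split gave 5201 clusters, 1873 genes, 520 start positions and 1010 main cluster shares, and the highest of the others gave 0 of each. It gave 7 gene lists, and the highest of the others 6.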
